A study of Mus musculus with 18 samples.

How the data were processed

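Total RNA from mouse cortex and hippocampus, 100 ng per sample, was amplified with a biotin label and hybridized to Illumina Mouse-6 V1 bead arrays by the authors. The deposited scanner export holds, for each of 18 arrays, an intensity per probe and a detection score per probe. Per the file headers the intensity was exported without normalization. The detection score, as deposited, runs up to 1 and ranks a probe's signal against that of negative controls. The submitters' notes name BeadStudio 2.0 and the header of the export names version 1.5.1.3, and which of them made the values stays unknown. The export held 108 further columns for the arrays, which were not used here.

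The deposited series values were read as an alternative only. In 17 of the 18 columns they equal the exported intensity minus a constant of 192 to 254 with dim cells left empty, and their column medians ran from 288.74 to 400.75. The column of control cortex 2 had nothing subtracted and a median of 593.9, and why it differed stays unknown.

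The deposited hybridization log placed the arrays on 3 slides, each with 6 arrays, 1 of each group. The replicate numbers in the titles equal the slides, so a replicate block is a slide block. Each group always sat at the same position on the slide, so position and group cannot be told apart. Arrays of 1 number resembled each other after the group means were removed: 31 of 45 pairs from different groups correlated above 0.1 (median 0.226), against 17 of 90 pairs of unlike number (median −0.0966). The labels call every sample male. The series description calls the CIH samples' mice CCH treated, while titles and sample descriptions say CIH, and the titles were followed.

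Intensities were processed with neqc in limma 3.58.1 under R 4.3.3, with background estimated from detection p (1 minus the deposited score), an offset of 16 and quantile normalization, on a log2 scale. Probes with a score above 0.99 on at least 3 of the 18 arrays were kept, which gave 14664 probes, 10713 of them detected on all 18. Control, vector and 18S rRNA probes were left out of the tests, and 18S was read from raw intensity. The lowest exported intensity was 36.5, and 3 arrays per group limit the precision.

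A linear model with a mean per group was fitted over all 18 arrays with lmFit and eBayes, without covariates, and p-values were two-sided and adjusted by Benjamini and Hochberg over the probes of a comparison. A probe was called at an adjusted p under 0.05. The comparisons were CCH and CIH against control and CIH against CCH in each tissue, the interactions of tissue with each exposure, and the control tissues with each other. Blocked counts add the slide to the same model. For a gene undetected in a group, the fold was bounded by the lowest detected signal and written as at least. No change is given for Sspn, whose intensities did not match its detection scores.

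A key joining probes to genes is not given in the sources used here. The number in zero-padded probe identifiers was read as an NCBI gene ID, matched to mouse gene names of GRCm38.p6. Of 11897 such identifiers 82.6% match a mouse gene, against 46.0% and 46.2% when the number is shifted by 1, and 32.9% and 33.4% when shifted by 100. Of 88 probes so named for ribosomal proteins 80.7% were detected, against 1.46% of 343 olfactory and 0 of 95 vomeronasal receptor probes. Names reached 4650 of the 14664 probes, 31.7%, for 4158 genes, and 68.3% stayed unnamed. Vegfa, Slc2a1, Bnip3, Alas2 and Mbp had no named probe, and Pdk1 and Ryr2 were not detected. Probes of the hemoglobin, histocompatibility and immunoglobulin genes may share signal with family members, which was not tested.

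There were 33 gene lists: HIF target genes, glycolysis, mitochondrial respiratory chain, antioxidant, acid-base and ion transport, calcium handling of the endoplasmic and sarcoplasmic reticulum, voltage-gated channel, synapse, immediate early, heat shock and unfolded protein response, apoptosis, proliferation, growth and IGF signalling, glucocorticoid response, interferon response, cholesterol synthesis, ribosomal protein, hemoglobin and erythroid, myelin and mature oligodendrocyte, oligodendrocyte precursor, astrocyte, microglia, endothelial, mural, meningeal fibroblast, ependymal, choroid plexus, excitatory neuron, interneuron, immature neuron, striatum, thalamus and skeletal muscle. The 20 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and 13 had too few genes. The lists, the test, the threshold, the comparisons, the alternatives not said to be added and the rule for named genes were chosen before the data were examined.

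The rule took, for each comparison with control, the 10 genes with the largest rise and the 10 with the largest fall among called probes whose 3 treated arrays all lay on the same side of the 3 control arrays, with 1 probe per gene and without clone or locus identifiers. Where fewer passed, the next by unadjusted p filled up to 5, each said not to pass. It also took up to 4 members of each passing list, 5 genes per direction in the other comparisons, and a fixed set, of which some items are not reported here (Vegfa, Slc2a1, Ldha, Pgk1, Bnip3, Pdk1, Hba-a1, Hbb-b1, Alas2, Mbp, Mog, Mobp, Gfap, Ryr2 and Atp2a2). Xist, Kdm5d, Mt1, Mt3, Enpp2 and the striatum and thalamus genes were named after their values were seen.

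The procedure was tested on simulated data in which changes were added to the CCH cortex comparison: 79.1% of 67 probes changed by 0.5 log2 units were called, 98.5% of 67 changed by 1 and 100% of 66 changed by 2, with 11 of 196 calls false. An unchanged comparison gave 0 calls, and 4.3% of 1000 random lists had a p under 0.05. The simulated noise was drawn independently for each probe, so the 4.3% does not hold for lists whose genes vary together. To size the effect of shared controls and of arrays with the same number in both tissues, 100 data sets without any change were simulated for each from the arrays' residuals; the simulations of same signs, with slides kept, and those of the tissues were added after the data were seen.

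The alternatives were other background corrections, offsets and normalizations, the authors' values, other filters, fits to the compared groups alone, slide blocks, array weights, an intensity trend, robust eBayes, a fold threshold of 1.5, probe means, estimated correlation and leaving out each array in turn. Another 4 were added after the data were seen: the 13 arrays with low Xist alone, Xist as a covariate, the authors' values without control cortex 2, and the data without the 3 arrays farthest from 0 on the second principal component. Tables and plots used version 1.17.8 of data.table, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.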

Results

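RNA from the cortex and hippocampus of CD-1 mice aged 16 days was measured on 18 bead arrays carrying 46120 probes. The arrays formed 6 groups of 3: control, chronic consistent hypoxia (CCH) and chronic intermittent hypoxia (CIH), in each tissue. Both exposures began at postnatal day 2 and lasted 2 weeks per the labels, and the oxygen levels and cycle are not given in the sources used here. Median raw intensity was 70.8 to 96.4 per array, and 12248 to 14527 probes were detected per array. The first principal component, which separated cortex from hippocampus, held 41.5% of the variance, and the second held 12.6%. Replicate arrays correlated at r = 0.982 to 0.995 over 18 pairs. On the second component CCH cortex 1 (20.8), CIH cortex 2 (−17.9) and control hippocampus 3 (−16.0) lay farthest from 0 of the 18 arrays; within control hippocampus, array 1 (6.99) was farther from array 2 (−8.39) than array 3 was. Nothing in the labels states that the replicates were separate animals, so the p-values measure spread between samples, which may be technical in part.

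Xist, the noncoding RNA that silences an X chromosome in females, and Kdm5d, a histone demethylase encoded on the Y chromosome, moved apart between arrays although every sample was labelled male. Xist lay at 9.36 to 10.18 log2 units on 5 arrays (CCH cortex 2 and 3, CIH cortex 2, CCH hippocampus 3 and CIH hippocampus 2) and at 6.53 to 6.57 on the other 13. Kdm5d was detected on 0 of those 5 arrays, at 6.46 to 6.51, and on 12 of the other 13, at 6.71 to 6.93. None of the 6 control arrays was among the 5 arrays with high Xist, so Xist level and hypoxia overlap in part. Each hypoxia group held arrays with high and with low Xist, which argues against its 3 arrays being repeats of 1 RNA sample. For arrays of like Xist, the 6 control arrays among them, repeats of a sample stay possible.

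**Figure D1:**
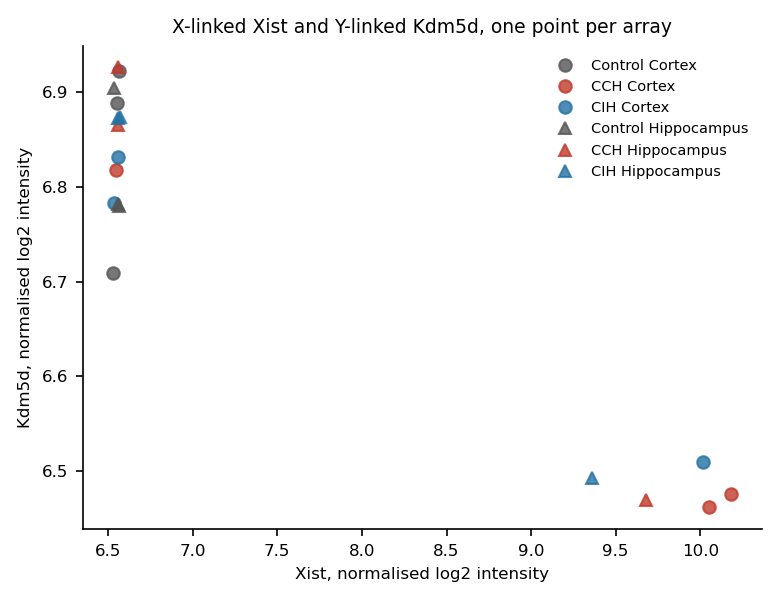
Log2 signal of Xist (x axis) against log2 signal of Kdm5d (y axis), with 1 point per array. Colours mark control, CCH and CIH, and circles mark cortex and triangles hippocampus. The 5 arrays with Xist at 9.36 to 10.18 have Kdm5d at 6.46 to 6.51, below all 13 others.

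In cortex, CCH against control asked how continuous hypoxia changed expression. Acer2, a ceramidase that releases sphingosine, rose 4.75-fold (log2 change 2.25 ± 0.12 SE, n = 3 per group), from 7.21 ± 0.13 (SD) to 9.45 ± 0.24. Fgfr1op2 rose 5.24-fold (log2 change 2.39 ± 0.12), and the hemoglobin transcripts Hba-a1 (1.26 ± 0.13) and Hbb-b1 (1.12 ± 0.20) rose with it. Ddah1, which breaks down an endogenous inhibitor of nitric oxide synthase, rose 2.08-fold (1.05 ± 0.14). Nudt19, a coenzyme A hydrolase, fell by 1.83 ± 0.15 on the log2 scale, from 11.40 ± 0.03 to 9.57 ± 0.07. Padi2, a peptidylarginine deiminase of oligodendrocytes, fell by 1.09 ± 0.10, and the immunoglobulin heavy chain transcript Ighm fell by 1.85 ± 0.24.

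In that comparison 124 of 14664 probes were called, 67 higher and 57 lower, and 39 of these carried a gene name. The adjusted p was 1.2e-07 for both Acer2 and Fgfr1op2, 0.00016 for Hba-a1, 0.018 for Hbb-b1, 0.0015 for Ddah1, 3.6e-05 for Nudt19, 6.2e-05 for Padi2 and 0.0015 for Ighm. Other named rises were Epc1, part of a histone acetyltransferase complex (0.75), Shoc2, a scaffold of Ras signalling (0.55), the glycolytic enzyme Eno1 (0.53), the endothelial adhesion molecule Pecam1 (0.39) and the splicing factor Sfpq (0.39). Other named falls were Brat1 (−1.24), the corepressor Cbfa2t3 (−1.12), the immediate early factor Egr2 (−0.97), the oligodendrocyte membrane protein Opalin (−0.70), Tmem125 (−0.69), the lysophosphatidic acid receptor Lpar1 (−0.68) and the glycine transporter Slc6a9 (−0.64). The second detected probe of Fgfr1op2 gave −0.02, so its rise rests on 1 probe.

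The myelin and mature oligodendrocyte list lay lower in CCH cortex: all 10 measured genes were below control, with a median of −0.45 (−0.70 to −0.05). Opalin, the tetraspanin Tspan2 (−0.53) and Evi2a (−0.33) were called over all probes, and 7 genes when adjusted over the list alone. Fa2h, which makes the hydroxylated fatty acids of myelin lipids, was at −0.68 (adjusted p = 0.069), and Enpp6 at −0.60 (adjusted p = 0.13). The list's adjusted p was 3.9e-08 in camera with the preset correlation and 0.087 with an estimated correlation, and the medians within the 3 slides were −0.35, −0.63 and −0.43. The mean log2 signal of the 10 genes was 9.33 ± 0.06 (SD, n = 3) in control cortex and 8.91 ± 0.08 in CCH cortex.

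Cholesterol synthesis genes also lay lower in CCH cortex, with 11 of 11 below control and a median of −0.20 (−0.42 to −0.02), including the sterol demethylase Cyp51 (−0.42) and the regulator Srebf2 (−0.32). None of them was called over all probes in limma, where 1587 probes had an unadjusted p under 0.05, 3 were when adjusted over the list alone, and the list's adjusted p was 0.00042, or 0.012 with an estimated correlation. Endothelial genes lay higher, 6 of 6, with a median of 0.29 (0.11 to 0.60), Pecam1 called, and Eng, a receptor component of the TGF-beta family, at 0.60 (adjusted p = 0.067), or 0.38 without CCH cortex 1. Their adjusted p was 8.5e-05, or 0.012 with an estimated correlation. Of 15 glycolysis genes, 12 were above control (median 0.14), with Eno1 called, Pfkl at 0.46 and Ldha, which makes lactate, at 0.35. The adjusted p of glycolysis was 0.003, or 0.025 with an estimated correlation. The mitochondrial respiratory chain list, 24 of 34 above control (median 0.07), had an adjusted p of 0.038 and an adjusted p of 0.52 with an estimated correlation. Hemoglobin transcripts, which blood in the tissue also carries, were higher in the same arrays, with a median of 1.26 over 3 genes and 2 called. Over the 13 arrays with low Xist, which leave CCH cortex 1 alone in its group, the endothelial median was 0.10 and its call ended (adjusted p = 0.0545), as did those of cholesterol synthesis and glycolysis (adjusted p = 0.18 for each), while the myelin list still passed. The 18S rRNA signal was 5427.8 to 7530.2 in CCH cortex and 9019.8 to 9956.9 in control cortex.

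With the slide as a block 173 probes were called in CCH cortex, 112 of them in both fits, and of the named calls Eno1 no longer passed (adjusted p = 0.053). The groups did not overlap at 15.1% of probes, where chance gives 10%; without control cortex 1 the count was 62, without control cortex 3 it was 64, and without CCH cortex 1 or CCH cortex 3 it was 69.

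**Figure D2:**
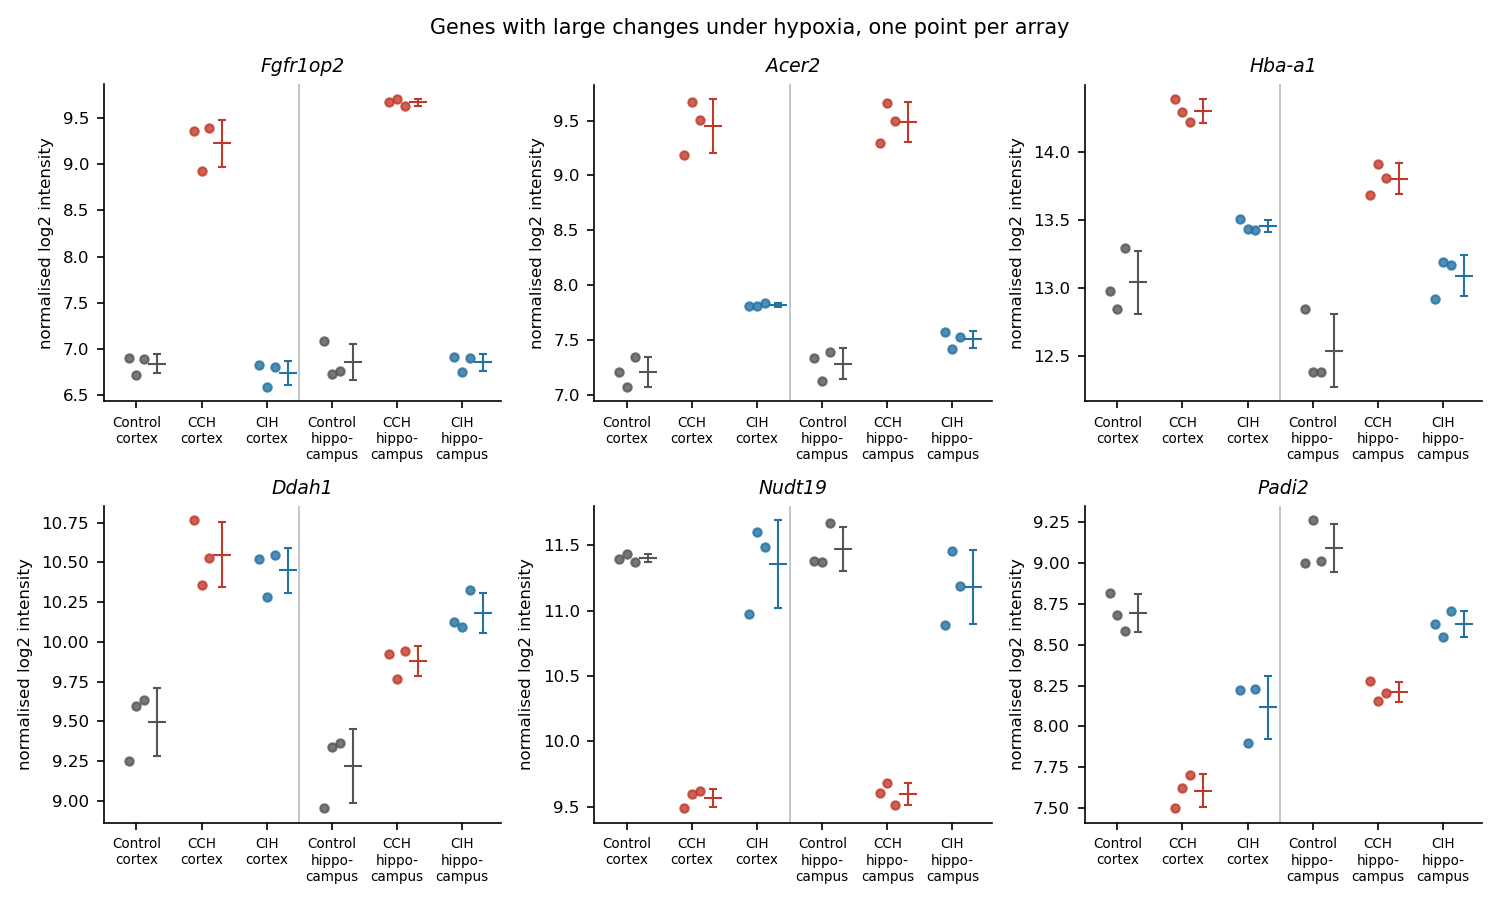
Log2 signal (y axis) of Fgfr1op2, Acer2, Hba-a1, Ddah1, Nudt19 and Padi2 in the 6 groups (x axis), with points for arrays and bars for mean ± SD, n = 3. Acer2 lies at 9.45 in CCH cortex and 7.21 in control cortex, and Nudt19 at 9.57 and 11.40.

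CIH against control in cortex asked the same of intermittent hypoxia. Ddah1 rose 1.94-fold (log2 change 0.95 ± 0.14 SE, n = 3 per group), from 9.49 ± 0.21 (SD) to 10.45 ± 0.14, and Krt12, a keratin best known from the corneal epithelium, rose 3.26-fold (1.70 ± 0.22). Ighm fell by 1.58 ± 0.24 on the log2 scale. Egr2 (−0.88 ± 0.15) and the AP-1 subunit Fosl2 (−0.67 ± 0.12), both immediate early genes, fell. Dctn4, a dynactin subunit, fell by 0.78 ± 0.08, and Pop4, a subunit of ribonuclease P, fell by 1.29 ± 0.22.

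In that comparison 22 probes were called, 10 higher and 12 lower, 10 of them named. The adjusted p was 0.0065 for Krt12, 0.013 for Ddah1, 0.001 for Dctn4, 0.02 for Ighm, 0.037 for Pop4 and 0.044 for both Egr2 and Fosl2. Padi2 fell by 0.58 (adjusted p = 0.037). H2-Bl, a class I histocompatibility gene, was detected on 2 of 3 CIH arrays and on 0 of 3 control arrays, at least 1.09-fold higher (adjusted p = 0.037). The probe of the sarcospan gene Sspn was called too, but it was detected on 0 of 3 CIH arrays and its intensities did not match its detection scores, so no change is given. H2-D1, another class I gene, was at least 3.03-fold higher but did not pass (adjusted p = 0.06), nor did the galactosyltransferase B3galt6 (at least 1.67-fold, adjusted p = 0.06). Both also lay above control on the CCH cortex arrays, H2-D1 at 7.70 to 8.22 and B3galt6 at 7.22 to 7.30 log2 units. In CCH hippocampus they lay at 6.54 and 6.59 on array 2, but H2-D1 was at 7.67 and 8.03 and B3galt6 at 7.50 and 7.42 on arrays 1 and 3. Hba-a1 was at 0.41 (adjusted p = 0.43), Hbb-b1 at 0.04 and Ldha at 0.04.

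Myelin genes lay lower in CIH cortex, 10 of 10, with a median of −0.33 (−0.53 to −0.09), including Trf, the iron carrier transferrin (−0.53), Fa2h (−0.52) and Mog (−0.47, or −0.28 without CIH cortex 1). None was called over all probes in limma, where 935 had an unadjusted p under 0.05, and 5 were when adjusted over the list alone; the adjusted p was 1.6e-07, and the adjusted p was 0.21 with an estimated correlation. Within slides the medians were −0.50, −0.37 and −0.26. All 6 heat shock genes were below control, with a median of −0.10 and Hspb1, a small chaperone, at −0.31 (adjusted p = 0.13); the list's adjusted p was 0.0045, and the adjusted p was 0.073 with an estimated correlation. The immediate early list had a median of −0.01 and a mean of −0.27 over 5 genes, with Egr2 and Fosl2 called. Its adjusted p was 0.015, the adjusted p was 0.22 with an estimated correlation, and with slides blocked it was 0.052.

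With the slide as a block 23 probes were called in CIH cortex, 16 in both fits, and Pop4 (0.062), Fosl2 (0.062), Padi2 (0.052) and the Sspn probe (0.069) no longer passed on adjusted p. The groups did not overlap at 12.5% of probes (10% by chance), and the count was 4 without CIH cortex 1, 7 without CIH cortex 2 or without control cortex 1, and 10 without control cortex 3.

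CCH against control in hippocampus posed the question of continuous hypoxia in the other tissue. Fgfr1op2 rose 7.06-fold (log2 change 2.82 ± 0.12 SE, n = 3 per group), from 6.85 ± 0.20 (SD) to 9.67 ± 0.04, and Acer2 rose 4.60-fold (2.20 ± 0.12). The hemoglobin transcripts Hbb-b2 (1.80 ± 0.33), Hba-a1 (1.26 ± 0.13) and Hbb-b1 (1.10 ± 0.20) rose. Nudt19 fell by 1.88 ± 0.15 on the log2 scale and Cbfa2t3 fell by 1.35 ± 0.21. Myelin-related genes fell as well, among them Fa2h (−1.21 ± 0.16), Padi2 (−0.88 ± 0.10), Tspan2 (−0.83 ± 0.11) and Opalin (−0.72 ± 0.12).

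In that comparison 76 probes were called, 45 higher and 31 lower, 29 of them named. The adjusted p was 1.4e-08 for Fgfr1op2, 1.6e-07 for Acer2, 0.02 for Hbb-b2 and Hbb-b1, 0.00021 for Hba-a1, 1.8e-05 for Nudt19, 0.0073 for Cbfa2t3, 0.0021 for Fa2h and 0.00037 for Padi2. Further rises were Hopx (0.73), the oxidant-gated cation channel Trpm2 (0.73), Ddah1 (0.66), the lysosomal mannosidase Man2b1 (0.46) and the peroxidase Prdx1 (0.45). Further falls were Trf (−0.99), Cpne9 (−0.64), the oligodendrocyte gene Bcas1 (−0.58) and Slc6a9 (−0.57).

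All 10 myelin genes were below control in CCH hippocampus, with a median of −0.68 (−1.21 to −0.21). Of these 5 were called over all probes and 9 when adjusted over the list alone, and the adjusted p was 1.7e-16, or 0.013 with an estimated correlation. Mog was at −0.94 (adjusted p = 0.11) and Mobp at −0.31, or −0.13 without CCH hippocampus 2. Within slides the medians were −0.77, −1.12 and −0.25. The mean log2 signal of the 10 genes was 9.03 ± 0.18 (SD, n = 3) in control and 8.35 ± 0.22 in CCH hippocampus.

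Cholesterol synthesis genes lay lower in 10 of 11 cases (median −0.15), with the lanosterol synthase Lss at −0.42 and Acat2 at −0.31. None of them was called over all probes in limma, where 1231 probes had an unadjusted p under 0.05, and 3 were when adjusted over the list alone. The list's adjusted p was 0.00042, or 0.012 with an estimated correlation. All 6 endothelial genes were above control (median 0.27), with Eng and Robo4, a guidance receptor of vessels, both at 0.46, and an adjusted p of 9.8e-06, or 0.0059 with an estimated correlation. Hemoglobin transcripts had a median of 1.26 in the same arrays, with 3 of 3 called. Glycolysis, 12 of 15 above control with a median of 0.05, had an adjusted p of 0.019 and an adjusted p of 0.054 with an estimated correlation. The astrocyte list, 5 of 5 below control with a median of −0.17 and the water channel Aqp4 at −0.55 (adjusted p = 0.14), had an adjusted p of 0.046, an adjusted p of 0.14 with an estimated correlation, and 0.065 with slides blocked.

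With the slide as a block 95 probes were called in CCH hippocampus, 69 in both fits, and Hopx (0.054), Man2b1 (0.056) and Trf (0.063) no longer passed on adjusted p. The groups did not overlap at 12.2% of probes (10% by chance), and without control hippocampus 1 the count was 126.

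**Figure D3:**
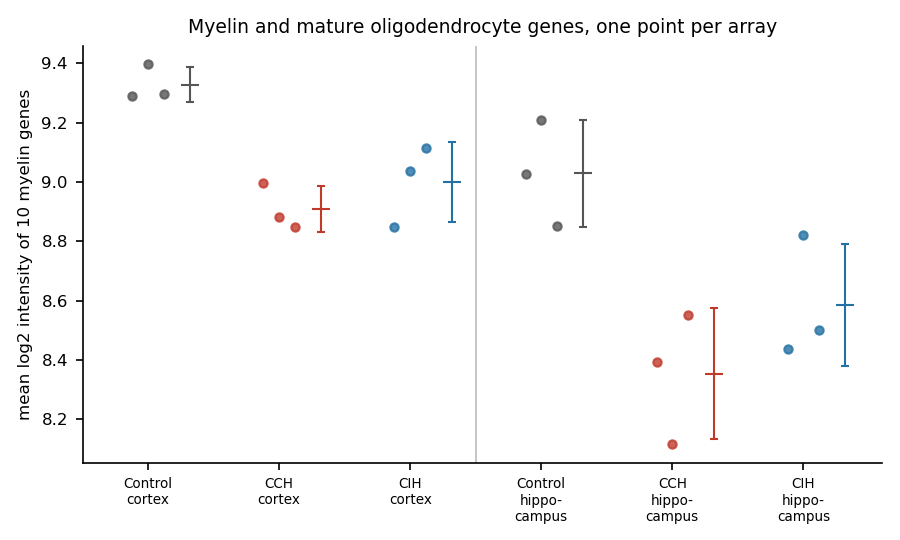
Mean log2 signal of the 10 measured myelin genes (y axis) in the 6 groups (x axis), with points for arrays and bars for mean ± SD, n = 3. The cortex means are 9.33 in control and 8.91 in CCH, and the hippocampus means are 9.03 in control, 8.35 in CCH and 8.59 in CIH.

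In CIH against control in hippocampus, Ddah1 rose 1.95-fold (log2 change 0.96 ± 0.14 SE, n = 3 per group), from 9.22 ± 0.23 (SD) to 10.18 ± 0.13. Pop4 fell by 1.65 ± 0.22 on the log2 scale and Dctn4 fell by 0.79 ± 0.08. Of 9 called probes, 4 higher and 5 lower, 4 carried a gene name: these 3 genes, with an adjusted p of 0.01 for Ddah1, 0.0059 for Pop4 and 0.0013 for Dctn4, and the Sspn probe, detected on 0 of 3 CIH arrays and given no change for the same reason as in cortex. H2-D1 was at least 3.27-fold higher (adjusted p = 0.055), B3galt6 at least 1.70-fold higher (adjusted p = 0.058), Hba-a1 at 0.55 (adjusted p = 0.18), Zfp870 at 0.45 (adjusted p = 0.11), Brat1 at −1.14 (adjusted p = 0.054) and Hspb1 at −0.39 (adjusted p = 0.058), and none of these passed. The second detected probe of Dctn4 gave 0.02 here and 0.07 in CIH cortex, so its fall rests on 1 probe.

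Myelin genes lay lower in CIH hippocampus too, 10 of 10, with a median of −0.43 (−0.86 to −0.15), Trf at −0.86, Fa2h at −0.71 and Mog at −0.58. Of them 0 were called over all probes, where limma gave 937 probes an unadjusted p under 0.05, and 8 were when adjusted over the list alone; the adjusted p was 1e-10, and the adjusted p was 0.08 with an estimated correlation. Within slides the medians were −0.54, −0.38 and −0.39. All 10 immature neuron genes were above control (median 0.15), among them Tubb2b (0.47, or 0.19 without CIH hippocampus 2), Nnat (0.35) and Gap43 (0.28, or 0.11 without control hippocampus 2), with an adjusted p of 0.0022 and an adjusted p of 0.055 with an estimated correlation. Ribosomal protein genes, 31 of 38 above control with a median of 0.09, had an adjusted p of 2e-05 and an adjusted p of 0.44 with an estimated correlation. The respiratory chain, 23 of 34 above control with a median of 0.05, had an adjusted p of 0.023 and an adjusted p of 0.49 with an estimated correlation. With the slide as a block 10 probes were called, 9 in both fits. The groups did not overlap at 9.48% of probes, under the 10% that chance gives, and without control hippocampus 1 the count was 52.

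**Figure D4:**
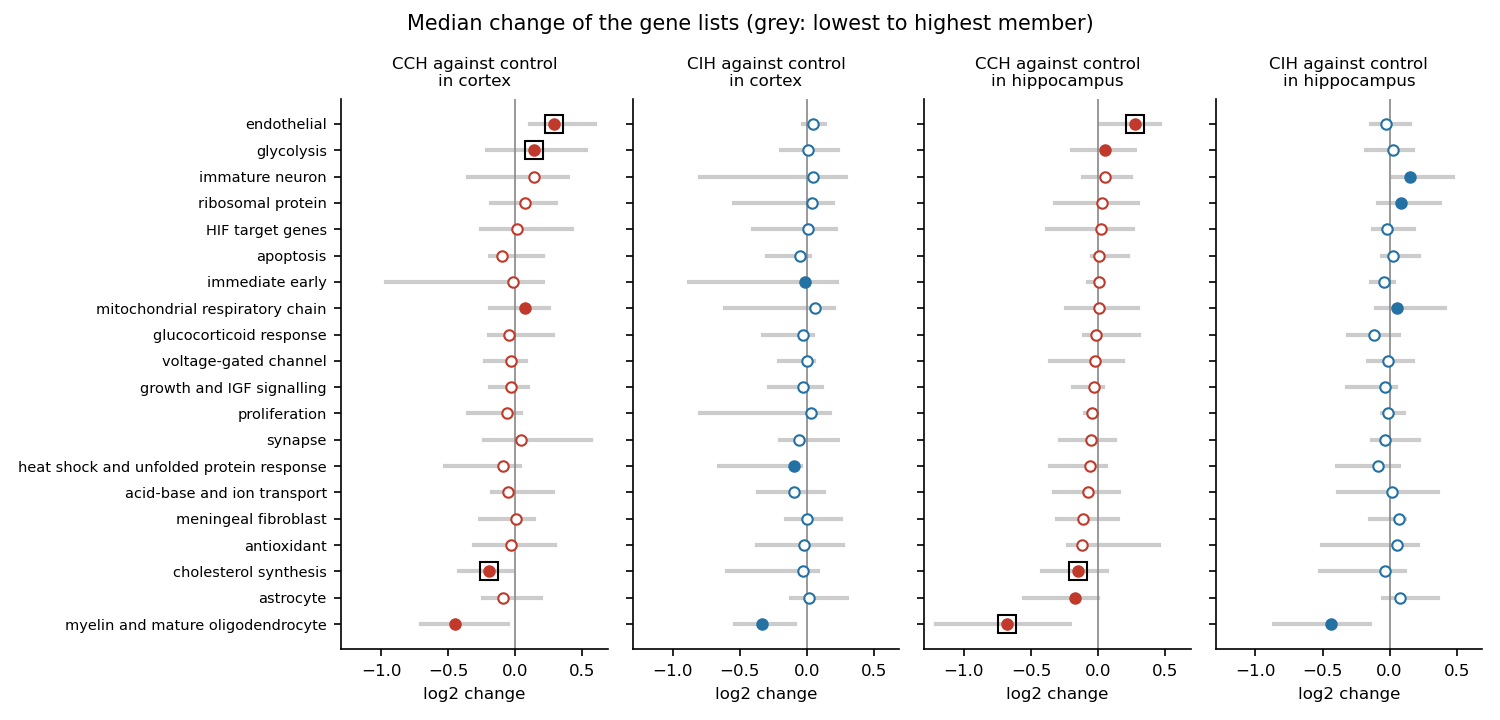
Median log2 change of 20 gene lists (y axis) in the 4 comparisons with control, on a log2 scale (x axis), with filled points for lists that passed camera, black squares for those that also passed with an estimated correlation, and grey lines from the lowest to the highest member. The myelin list has the lowest medians, −0.45, −0.33, −0.68 and −0.43.

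The remaining lists passed in none of the comparisons with control and are given as medians for CCH cortex, CIH cortex, CCH hippocampus and CIH hippocampus. HIF target genes, induced by the hypoxia-inducible factors, were at 0.01, 0.01, 0.02 and −0.02 (11 genes). Acid-base and ion transport was at −0.06, −0.10, −0.08 and 0.02 (8 genes), antioxidant at −0.03, −0.02, −0.12 and 0.05 (8), and apoptosis at −0.10, −0.05, 0.01 and 0.02 (7). Glucocorticoid response was at −0.04, −0.03, −0.01 and −0.11 (6), growth and IGF signalling at −0.03, −0.02, −0.03 and −0.03 (7), and meningeal fibroblast at 0.01, −0.00, −0.12 and 0.07 (6). Proliferation was at −0.06, 0.04, −0.05 and −0.01 (6), synapse at 0.04, −0.05, −0.06 and −0.03 (16), and voltage-gated channel at −0.03, 0.00, −0.02 and −0.01 (13). Prdx1 of the antioxidant list was called in CCH hippocampus. The astrocyte marker Gfap was at −0.09, −0.01, −0.17 and 0.08, and the calcium pump Atp2a2 at −0.17, −0.43, 0.08 and 0.14. For Atp2a2, CIH cortex was at −0.13 without CIH cortex 2, and CCH hippocampus ran from −0.10 to 0.29 when single arrays were left out. The glycolytic enzyme Pgk1 was at 0.09, −0.19, −0.00 and 0.03.

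The lists with fewer than 5 measured genes were not tested and are given as the same 4 medians. Hemoglobin was at 1.26, 0.13, 1.26 and 0.55 (3 genes), choroid plexus at −0.00, 0.05, −0.04 and −0.32 (4) and calcium handling of the reticulum at 0.03, −0.04, 0.02 and 0.14 (3). Ependymal was at −0.07, 0.12, 0.14 and 0.09 (1), excitatory neuron at 0.23, 0.02, −0.16 and 0.02 (4), interferon at 0.09, 0.01, 0.01 and −0.02 (4), and interneuron at 0.31, 0.17, −0.07 and 0.01 (2). Microglia was at 0.08, −0.00, 0.17 and −0.02 (3), oligodendrocyte precursor at 0.14, 0.04, −0.11 and 0.04 (2), and skeletal muscle at 0.05, 0.07, −0.04 and 0.00 (2). Striatum was at 0.02, −0.02, −0.10 and −0.09 (2), thalamus at −0.03, −0.16, −0.38 and −0.14 (3), and the mural list had 0 measured genes.

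CIH against CCH asked where the exposures differed. In cortex Nudt19 was higher under CIH by 1.79 ± 0.15 log2 units (SE, n = 3 per group), Krt12 by 1.52 ± 0.22, the sulfatase Arsa by 0.67, the G protein regulator Rgs8 by 0.58 and Padi2 by 0.51. Fgfr1op2 (−2.49 ± 0.12), Acer2 (−1.63 ± 0.12), Pop4 (−1.11), Hbb-b1 (−1.08) and Fstl5 (−1.04) were lower under CIH. In hippocampus Nudt19 (1.58 ± 0.15), Cbfa2t3 (1.23), the astrocyte water channel Aqp4 (0.89), Mzt1 (0.78) and the initiation factor Eif5 (0.39) were higher, and Fgfr1op2 (−2.82 ± 0.12), Acer2 (−1.98 ± 0.12), Pop4 (−1.42), Dctn4 (−0.83) and Txnl4a (−0.73) were lower; the second detected probe of Txnl4a gave 0.06, so its fall rests on 1 probe. The adjusted p was 3e-05 for Nudt19, 7.8e-08 for Fgfr1op2 and 0.00061 for Rgs8 in cortex, and 0.00018 for Nudt19, 1.4e-08 for Fgfr1op2 and 0.015 for Aqp4 in hippocampus. In cortex 69 probes were called, 36 higher and 33 lower under CIH, and in hippocampus 42, 14 higher and 28 lower.

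Endothelial genes were lower under CIH than CCH in both tissues, 6 of 6, with medians of −0.21 in cortex (adjusted p = 0.00087, or 0.015 with an estimated correlation) and −0.24 in hippocampus (2.9e-05, or 0.0068). The mean log2 signal of the hemoglobin transcripts was 9.82 to 10.26 on the CIH arrays and 10.87 to 11.30 on the CCH arrays in cortex, and 9.72 to 10.02 and 10.77 to 10.90 in hippocampus. Glycolysis was lower in cortex, 12 of 15 genes, with a median of −0.14 (adjusted p = 0.00087, or 0.015 with an estimated correlation). Over the 13 arrays with low Xist, where CCH cortex 1 stands alone, the endothelial median in cortex turned to 0.02 and the calls of both lists ended there (adjusted p = 0.31 and 0.32). Astrocyte genes were higher under CIH in hippocampus, 5 of 5, with a median of 0.25 (adjusted p = 0.00026, or 0.018 with an estimated correlation). Myelin genes, 9 of 10 higher in hippocampus with a median of 0.24, had an adjusted p of 0.0015 and an adjusted p of 0.33 with an estimated correlation, and the medians within slides were 0.04, 0.77 and −0.10. Cholesterol synthesis (median 0.15) and ribosomal protein genes (median 0.09) had an adjusted p of 0.015 and 0.0025, and an adjusted p of 0.069 and 0.49 with an estimated correlation.

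With the slide as a block 80 probes were called in cortex and 42 in hippocampus, and Padi2 (0.051) and Pop4 (0.066) in cortex and Cbfa2t3 (0.058) in hippocampus no longer passed on adjusted p. The groups did not overlap at 13.9% and 13.6% of probes (10% by chance); the cortex count was 31 without CIH cortex 2, 35 without CIH cortex 3, 37 without CCH cortex 3 and 42 without CIH cortex 1 or CCH cortex 1, and the hippocampus count was 24 without CIH hippocampus 3, 26 without CCH hippocampus 1 and 27 without CIH hippocampus 2.

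Ddah1 was called higher under both exposures in both tissues, and Padi2, Egr2, Ighm and Fosl2 (−0.55 under CCH) were called lower under both in cortex. The CCH hippocampus call of Ddah1 was lost in 12 of the 18 alternatives not added in which it was scored. Among these were the fits without any 1 of the compared arrays. The Sspn probe, for which no change is given, was 1 of the lower calls shared in each tissue. In cortex 4 higher and 7 lower probes were called under both exposures, where chance gives 0.0457 and 0.0466, and in hippocampus 3 and 2, where chance gives 0.0123 and 0.0106. Across 14664 probes, which are not independent replicates, the log2 changes correlated at r = 0.461 in cortex (Spearman's rho 0.409, covariance 0.0126) and 0.563 in hippocampus (rho 0.473, covariance 0.0137). Both exposures were compared with the same 3 control arrays. In 100 simulations without any change r was 0.497 on average (0.0166 to 0.896). Covariance there was 0.00903 on average and at most 0.0288. At most 5 calls were shared in a direction, which the 7 lower calls in cortex exceed and the other counts do not. These simulations drew arrays from any slide, while each real group holds 1 array per slide. Their 5 shared calls therefore cannot decide whether the other counts lie within chance. Of the 124 probes called under CCH in cortex 107 had the same sign under CIH, 86.3%, and of the 76 in hippocampus 70, 92.1%; the most changed probes of 100 further simulations without any change, in which each group took 1 array from each slide, gave 84.5% and 85.1% on average and up to 100%, so these shares do not show a shared response. With slides so kept r averaged 0.459, and the covariance averaged 0.00644 and reached 0.0165. There limma gave 0 shared calls in either direction, which is close to fixed in advance where nothing changes. Within slides r was 0.462, 0.539 and 0.593 in cortex and 0.504, 0.438 and 0.664 in hippocampus.

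Cortex and hippocampus shared 30 higher and 20 lower calls under CCH, where chance gives 0.206 and 0.12. They shared 4 and 4 under CIH, where chance gives 0.00273 and 0.00409. Chance here treats probes as separate transcripts. Several unnamed RIKEN clone probes among the 30 rose by 1.20 to 1.38 in cortex and 1.32 to 1.58 in hippocampus, near Hba-a1 (1.26 in both). The 30 may therefore hold repeats of a transcript, which was not tested. Arrays of the same number resembled each other between tissues (above r = 0.1 in 8 of 9 pairs, against 2 of 18 of unlike number), and 100 simulations without any change that kept these pairs gave 0 shared calls in limma in each direction. Few probes pass limma where nothing changes, so this count cannot size how far the pairs raise sharing among called probes. Fgfr1op2, Acer2, Hba-a1, Hbb-b1 and Ddah1 were called higher under CCH in both tissues, and Nudt19, Cbfa2t3, Padi2, Opalin, Tspan2 and Slc6a9 lower. Of the 124 CCH cortex calls 118 had the same sign in hippocampus, 95.2%, with a median ratio of 0.699, where the simulations gave 62.3% on average and at most 92.7%. All 22 CIH cortex calls did, with a median ratio of 0.795, where they gave 64.6% on average and at most 100%.

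The interaction, the hippocampus response minus the cortex response, asked whether the tissues differed. Egr2 differed by 0.89 ± 0.22 log2 units (SE) for CCH and by 0.80 ± 0.22 for CIH, Krt12 by −1.30 ± 0.32 and Fosl2 by 0.63 ± 0.17 for CIH, and none of these passed (adjusted p = 1 for each). The lowest detected signal on the control hippocampus arrays was 6.71 to 6.76. Egr2 lay at 6.70 to 6.80 there, so it had little room to fall in hippocampus. Krt12 lay below that limit, at 6.55 to 6.66, so its difference is not exact. In limma 0 probes were called for either exposure, with 670 and 383 at an unadjusted p under 0.05, and 0 with the slide as a block. None of the 20 lists passed, and the myelin list differed by −0.24 (adjusted p = 0.19) for CCH and −0.09 (adjusted p = 0.46) for CIH.

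Control hippocampus against control cortex gave the difference between the tissues themselves. Fibcd1 was 9.75-fold higher in hippocampus (log2 difference 3.29 ± 0.25 SE, n = 3 per group, adjusted p = 8.2e-07), C1ql2, a synaptic organiser of dentate gyrus mossy fibres, was higher by 2.70 ± 0.16 and Olfml2b by 2.33 ± 0.06 (adjusted p = 3.5e-11). The probe named for the T cell receptor segment Trbv31 was 12.3-fold lower (−3.62 ± 0.13, adjusted p = 4.5e-10), and the dopamine receptor gene Drd1 (−2.15 ± 0.08) and the transcription factor gene Mef2c (−1.94 ± 0.17) were lower. Serpina3n (2.37) and Dgkg (2.22) were higher, and Hs3st2 (−2.26) and Cobl (−2.26) lower. Myelin genes lay lower in hippocampus, 10 of 10 with a median of −0.23, an adjusted p of 0.013 and an adjusted p of 0.78 with an estimated correlation. In all 1711 probes were called, 808 higher and 903 lower in hippocampus, 501 of them named, and 1905 with the slide as a block; the groups did not overlap at 26.8% of probes (10% by chance).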

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

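The Xist and Kdm5d tests, the comparison of several probes of the same gene and the count of neighbours without Sspn were chosen only after the result was seen.

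On 5 arrays labelled male Xist was high, and on all 5 of them Kdm5d lay below every other array, which is what tissue of female mice would give. The gap between the Kdm5d ranges was 0.20 log2 units, which argues against Xist raised by hypoxia in male tissue, since Kdm5d would then lie within the range of the other arrays. Kdm5d was detected on 0 of those arrays, but it lay near the detection limit on the others too, at 6.71 to 6.93. The lowest detected signal of an array was 6.68 to 6.76, and Kdm5d was undetected on control cortex 2, where Xist was low. Its absence therefore cannot tell female tissue from RNA of male and female mice mixed in a sample. Female tissue among samples labelled male, alone or mixed with male tissue, may be the source, as a hypothesis found and tested on the same arrays. CCH 2 carried high Xist in cortex and not in hippocampus, the only such case among 9 pairs of arrays with the same number, so those numbers may not stand for the same animal in both tissues.

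Under CCH 50 probes were called alike in cortex and hippocampus, 30 higher and 20 lower, and under CIH 8 were. Under CCH 21 were at 2-fold or more in both tissues, Fgfr1op2, Acer2, Nudt19 and the hemoglobin transcripts Hba-a1 and Hbb-b1 among them. Of the 50 probes 18 carried a gene name, and whether the unnamed probes read separate transcripts was not tested. Sex of the animals was not decided by the test run. Over the 13 arrays with low Xist the changes had a median ratio of 1.02 to those over all arrays, and the lowest was 0.842. CCH cortex 1 stood alone in its group there. The changes were thus also present on arrays with low Xist. But all 124 and 76 probes called under CCH in cortex and hippocampus had treated and control arrays that did not overlap. So had all 22 and 9 under CIH, and no control array had high Xist. A ratio near 1 was therefore largely fixed by the selection. Linked inherited variants of the litters were neither shown nor excluded: 6 of 20 such named genes had another within the 5 nearest measured genes (Slc6a9 and Tmem125 on chromosome 4, Sspn and Fgfr1op2 on chromosome 6, Nudt19 and Pop4 on chromosome 7), against 0.87 on average in 10000 random sets, of which a share of 0.0069 had as many, but without Sspn, whose probe gives no usable change, it was 4 of 19 (0.787 on average, a share of 0.0543), and Nudt19 was called alike under CCH and Pop4 under CIH. A sequence variant or transcript form under a probe cannot be told apart from a change of the gene, because only 2 of these genes had another detected probe, with a median ratio of −0.0306. A response to the exposure stays open as well, because the 93.1% that moved the same way under the other exposure share their control arrays and decide nothing.

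Myelin genes were lower under both exposures in both tissues. Sex of the animals was argued against as the whole cause outside CCH cortex. Over the 13 arrays with low Xist the list medians were −0.38 in CIH cortex, −0.78 in CCH hippocampus and −0.54 in CIH hippocampus. Over all arrays they were −0.33, −0.68 and −0.43. In CCH cortex the median was 0.849 of its value over all arrays, the lowest ratio, but it rests on CCH cortex 1 alone. An outlying array was argued against too, because without any 1 array the list median was at least 0.696 of its value over all arrays. Striatum or thalamus carried over into control tissue cannot be told apart from the shift: the median of Adcy5, Calb2, Rora, Drd1 and Tcf7l2 was at most 0.328 of the myelin median, but these 5 genes vary widely, and Tcf7l2, which thalamus expresses strongly, was at −0.38, −0.16, −0.51 and −0.49 in CCH cortex, CIH cortex, CCH hippocampus and CIH hippocampus. The share of white matter in each dissection was not tested, and the effect of hypoxia itself, or of body and brain growth, stays open. Fewer mature oligodendrocytes and lower expression per cell were not separated by any test run here.

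The arrays of 3 against 3 can be split in 10 ways, too few for a share under 0.05, and only 4 of those splits part all the slide pairs. In CCH cortex 1 split, the real one, gave as many as its 124 calls, and the highest other gave 0; in CIH cortex it was 1, with 22 calls and 0 in the highest other, and in CCH hippocampus 1, with 76 and 0. In CIH hippocampus 2 splits gave at least the 9 calls, and the other gave 27. That split parts fewer slide pairs, the splits that part all pairs gave 0 besides the real one, and the blocked count was 10, so the 27 calls point to a structure of the samples such as the slides. CIH against CCH gave 1 split in cortex (69 calls, highest other 11, or 0 among splits parting all pairs) and 1 in hippocampus (42 calls, highest other 0), and the control tissues gave 1 (1711 calls, highest other 37, or 0 among those parting all pairs).

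The myelin shift was largest in the real split in each comparison, 1 of 10 each time: 0.45 against 0.27 in the highest other for CCH cortex, 0.33 against 0.21 for CIH cortex, 0.68 against 0.51 for CCH hippocampus and 0.43 against 0.42 for CIH hippocampus, where the highest among splits parting all pairs was 0.20. For the interactions all 100 of 100 drawn splits gave at least the 0 calls of limma, which a count of 0 fixes in advance, so this says nothing about chance. The highest other gave 323 for CCH and 2 for CIH, and with the slide as a block the real count stayed 0 for both. Labels were drawn in each tissue separately. A split that exchanges them in 1 tissue alone adds the responses of the tissues instead of subtracting them. The 323 calls may therefore hold changes shared by both tissues, so they do not show a structure of the samples.

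The Sspn probe read 246 to 318 on the 12 hypoxia arrays with detection scores of 0.0179 to 0.219, where probes of like score read 48.4 to 65.8, and 344 to 467 on the 6 control arrays with scores of 0.997 to 0.999, so its scores do not match its intensity. On the hypoxia arrays the excess, such as 193 on CIH hippocampus 3 and 253 on CCH cortex 1, matched the constant subtracted from the same array in the other deposited table, 193 and 253.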

How the results depend on the processing

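The alternatives named below as added were chosen only after the result was seen, and the others before. No named call changed its sign, and no list passed in the opposite direction relative to the other probes. The medians of 3 passing lists did change sign: the respiratory chain in CCH cortex fell to −0.12 in the authors' values, where all probes shifted, and was also below 0 there without control cortex 2; immediate early genes in CIH cortex reached 0.02 with median scaling and were also above 0 without control cortex 2; and endothelial genes for CIH against CCH in cortex were at 0.02 over the 13 arrays with low Xist, where the call ended. Of 75 named calls 17 passed under every alternative not added in which they were scored. Robust eBayes, the fold threshold of 1.5 and probe means were not scored for named calls. Probe means would have drawn on the second probes of Fgfr1op2 (−0.02 in CCH cortex) and Dctn4 (0.07 in CIH cortex). Acer2, Fgfr1op2 and Nudt19 each entered the 17 for CCH against control and for CIH against CCH, in both tissues. The other 58 were lost in some, and 11 were lost with the replicate block. Among the 17, Fgfr1op2 was tested in 16 of 18 such alternatives, and Acer2, Ighm and Opalin in 17. Nudt19 was tested in all 18. Apart from added alternatives and left-out arrays, 100 of 135 counts of calls stayed within 1.5 times the value reported. These include the interactions, where 0 calls were reported and 0 again counted as kept. They also include the slide block again under the name replicate block, so the share overstates stability. Over all alternatives and left-out arrays, the count was kept in 14 of 25 for CCH cortex and 13 of 25 for CIH cortex. In hippocampus it was kept in 18 of 24 for CCH and 14 of 24 for CIH. In the authors' values the median of all probes moved by up to 0.43 log2 units, or 0.27 without control cortex 2, and under the other scalings by at most 0.0517. Signal over background limits what could be seen, since 10713 of 14664 tested probes were detected on all 18 arrays. Unless a sentence says otherwise, the cause was not tested.

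Requiring at least 1.5-fold, which by construction calls fewer, gave 62 probes in CCH cortex, 48 in CCH hippocampus, 37 and 24 for CIH against CCH in cortex and hippocampus, and 607 between control tissues. Array weights gave 341 in CCH cortex, 101 in CIH cortex, 126 in CCH hippocampus, 14 in CIH hippocampus, and 122 and 82 for CIH against CCH. Fitting only the groups compared, with fewer arrays to estimate spread, gave 38 in CCH cortex, 14 in CCH hippocampus, 0 in CIH hippocampus (limma), 33 and 20 for CIH against CCH, and 1135 between tissues. No detection filter gave 72 in CCH cortex, 6 in CIH cortex, 36 and 22 for CIH against CCH, 5 lists in CIH cortex and 4 for CIH against CCH in cortex. An intensity trend gave 42 in CIH cortex and 31 in CIH hippocampus, and normexp with offset 50 gave 53 and 28. Offset 50 in neqc gave 14 in CIH cortex. In CIH hippocampus cyclic loess gave 16 and median scaling 21. Median scaling split the tissue calls 956 to 688. No detection filter also ended the astrocyte call for CIH against CCH in hippocampus (adjusted p = 0.095). Probes detected on all 18 arrays gave 1 list in CIH cortex, and probe means 3 lists in CCH hippocampus.

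The authors' values gave 28 calls in CCH cortex (8 higher, 20 lower), 5 in CIH cortex (0 and 5), 18 in CCH hippocampus (15 and 3), 2 in CIH hippocampus (0 and 2), 4 (3 and 1) and 4 (2 and 2) for CIH against CCH, and 521 between tissues (34 and 487). There r between exposures in cortex was 0.566, the myelin shift was −0.81 in CCH cortex (adjusted p = 0.06) and −0.72 in CIH cortex (adjusted p = 0.0629), and 3 lists passed in CCH cortex, 3 in CCH hippocampus, 0 for CIH against CCH in cortex and 2 in hippocampus; cholesterol synthesis lost its call in CCH cortex and in CCH hippocampus (adjusted p = 0.18 in the latter). Without control cortex 2 (added) they gave 6 in CCH cortex, 3 in CIH cortex and 228 between tissues (50 and 178), myelin shifts of −0.73 (adjusted p = 0.0661) and −0.53 (adjusted p = 0.0813), and 1 list in CCH cortex and 0 in CIH cortex. With estimated correlation the myelin adjusted p was 0.0866 for −0.45 in CCH cortex, 0.211 for −0.33 in CIH cortex and 0.0799 for −0.43 in CIH hippocampus, and 3, 0, 3 and 0 lists passed in the comparisons with control and 2 for CIH against CCH in hippocampus. Over all alternatives the myelin adjusted p reached at most 0.0866 in CCH cortex, 0.211 in CIH cortex, 0.0127 in CCH hippocampus and 0.0799 in CIH hippocampus.

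The 13 arrays with low Xist (added) gave 743 calls in CCH cortex, where CCH cortex 1 remains alone in its group and is assumed to vary like the other groups, 3 in CIH cortex, 41 in CCH hippocampus, 3 in CIH hippocampus, 368 and 17 for CIH against CCH and 123 for the CCH interaction, with 2 lists in CCH cortex and 0 for CIH against CCH in cortex. The lists that lost their calls in CCH cortex there were endothelial (median 0.10, adjusted p = 0.0545), cholesterol synthesis and glycolysis (adjusted p = 0.18 for each) and respiratory chain. Xist as a covariate (added) gave 17 in CIH hippocampus and 5 lists in CIH cortex. Without the 3 arrays farthest from 0 on the second principal component (added) CIH against CCH in cortex gave 34 and the CIH interaction 1, while CCH cortex gave 84.

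Leaving out each array in turn gave 62 (without control cortex 1) to 117 calls in CCH cortex, where it was 64 without control cortex 3 and 69 without CCH cortex 1 or CCH cortex 3. It gave 4 (without CIH cortex 1) to 20 in CIH cortex, with 7 without CIH cortex 2 or control cortex 1 and 10 without control cortex 3. It gave 52 to 126 (without control hippocampus 1) in CCH hippocampus and 8 to 52 (also without control hippocampus 1) in CIH hippocampus. CIH against CCH gave 31 (without CIH cortex 2) to 49 in cortex, with 35 without CIH cortex 3, 37 without CCH cortex 3 and 42 without CIH cortex 1 or CCH cortex 1, and 24 (without CIH hippocampus 3) to 35 in hippocampus, with 26 without CCH hippocampus 1 and 27 without CIH hippocampus 2. The interactions gave 0 to 1 (without CCH hippocampus 1) and 0 to 0 calls in limma, and the tissues 1219 to 1707. The correlation between exposures was 0.344 to 0.591 in cortex and 0.475 to 0.729 in hippocampus. The myelin shift was −0.52 to −0.38 in CCH cortex, −0.38 to −0.26 in CIH cortex, −0.82 to −0.59 in CCH hippocampus and −0.55 to −0.30 in CIH hippocampus. Lists passing were 4 to 6 in CCH cortex, 2 to 5 (without control cortex 1) in CIH cortex, 4 to 6 in CCH hippocampus, 3 to 5 in CIH hippocampus, and 2 to 2 and 3 (without CIH hippocampus 2) to 7 for CIH against CCH.

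Among the passing lists, leaving out an array ended the call of the respiratory chain in CCH cortex (adjusted p = 0.6 without control cortex 2, and also without CCH cortex 1 or CCH cortex 3) and in CIH hippocampus (0.29 without control hippocampus 2, and also without control hippocampus 3 or CIH hippocampus 1), of immediate early genes in CIH cortex (0.2 without CIH cortex 1), of astrocyte genes in CCH hippocampus (0.25 without CCH hippocampus 2, and also without control hippocampus 1 or control hippocampus 2) and of glycolysis there (0.15 without control hippocampus 3, and also without CCH hippocampus 3). For CIH against CCH in hippocampus it ended cholesterol synthesis and myelin (0.095 and 0.21 without CCH hippocampus 2, and also without CIH hippocampus 2) and ribosomal proteins (0.37 without CCH hippocampus 3, and also without CIH hippocampus 1).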

Other observations

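The genes in this part were chosen only after their values were seen. The metallothionein gene Mt1, whose product binds zinc and copper, was at 0.28 and 0.31 under CCH and at −0.33 and −0.31 under CIH in cortex and hippocampus, none of which passed (adjusted p = 0.55, 0.66, 0.78 and 0.81). The difference between CIH and CCH was −0.61 in cortex and −0.62 in hippocampus (adjusted p = 0.13 and 0.18). Mt3, a metallothionein of neurons and astrocytes, went the other way, at −0.31 and −0.22 under CCH and 0.23 and 0.13 under CIH, and passed in none of these comparisons.

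Aqp4, the water channel of astrocyte endfeet, was at −0.55 under CCH and 0.33 under CIH in hippocampus, neither past the threshold against control, and at −0.20 and 0.30 in cortex. Enpp2, a secreted phospholipase of the choroid plexus, was at −1.42 in CCH cortex and −0.83 in CCH hippocampus (adjusted p = 0.53 and 0.91).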
